A study of Mus musculus with 16 samples.

How the data were processed

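The 6 libraries analysed are 3 Mock and 3 hymeglusin cultures of mouse CD4+ T cells after 2 days under pTh17 conditions. Per the labels' protocols, messenger RNA was purified on poly-T beads, fragmented, copied with random hexamers and made into libraries with no step that marks the strand. Per the submitters' processing notes the reads were processed with fastp, a read trimming tool; the aligner, the counting tool and their versions are not given in the sources used here. The authors deposited whole-number counts per gene, not normalized, for 54532 genes, with gene annotation beside them. Of the gene identifiers, 54495 occur in GENCODE M21, a GRCm38 annotation, and 98.3% of these have identical start and end there. Coordinates are given as GRCm38 positions from the deposited annotation. A spreadsheet had turned 27 gene symbols into dates, and these were restored from the gene identifiers. Where several identifiers carried the same symbol, it stayed with the one of the largest total count, and the other 103 identifiers were given their identifier beside the symbol. Every entry named a gene.

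The 5 wild-type and 5 HMGCS1 knockout libraries were not analysed here, so the comparison of knockout with wild type, the difference between the knockout and hymeglusin effects and their agreement were left out. Samples were grouped by their titles. Because the protocol marks no strand, reads from stretches that overlapping genes share cannot be told apart. Among the named genes, Hmgcs1, Rora, Ifng, Foxp3, Gata3, Tcf7, Tnfrsf9, Pfkp, Pfkm, Gapdh, Pdia6, Il2, Trdc and Timp1 overlap the span of another annotated gene with counts, introns included. Whether their exons overlap was not checked, and their values may be uncertain to that extent. Ifitm2 and Ifitm3 belong to the same gene family, and whether the counting split reads between them was not measured.

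Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0. Genes were kept by filterByExpr with its defaults, which left 13264 genes, and libraries were scaled by TMM. The groups were compared with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, two-sided) with Benjamini-Hochberg adjustment at 0.05. Unless another tool is named, an adjusted p of a gene comes from that test, and log2 fold changes are hymeglusin minus Mock with their standard errors. Levels are CPM, the counts scaled to TMM-adjusted library totals. Gene lists were tested with limma's camera on log2 CPM (prior count 2, inter-gene correlation 0.01, lists of at least 5 tested genes, Benjamini-Hochberg over lists), and again with a correlation estimated from the data. "Adjusted over the list alone" means that the Benjamini-Hochberg adjustment used the p-values of that list's genes and no others. A total of 36 lists were written before the data were examined, as were the tests between the groups, the rule for named genes and the alternatives other than the surrogate variable. The tests of other groupings and of a sterol depletion response, and the counts of Th17 core members under the alternatives, were chosen later. They cover sterol and fatty acid metabolism, helper T cell fates, T cell activation, energy metabolism, stress responses, proliferation, cytokine signalling and markers of other cells, and some genes stand in several lists. Among the genes the rule names in every case are Hmgcs1, Il17a, Il17f, Il23r, Csf2, Ifng, Tbx21 and Foxp3; some other named genes are not reported here. It also names the largest changes among called genes without overlap between the groups, of which there were 0, and per list up to 2 members with the smallest p where none was called over all genes. Not every gene that the rule names is printed for the lists without a call. Ifitm3, Ifitm2, Timp1, Itga3, Plin2, Ccl22, Il22, Il2, Egln3, Slc16a3, Gapdh, Cd8a and Cd8b1 fall outside the rule and were chosen after their values were seen.

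Total counts ranged from 13750407 to 16858779 per library, and a floor of 3 counts in a library corresponds to 0.178 to 0.218 CPM; this floor covers counting error only. Pairs of libraries of the same group differed by 8.27 to 32.2 times the sampling noise (chi-square per degree of freedom over genes), and no library was counted as a repeat of another. Some pairs across the groups lay closer, the closest being Mock replicate 2 with hymeglusin replicate 3 (5.46). The ratio cannot tell separate cultures from separately prepared libraries of the same culture, which also exceed counting noise. On counts simulated from these libraries with known changes, over 13264 genes, the edgeR test recovered 28% of 50 genes changed 1.5-fold, 60% of 50 changed 2-fold, 86% of 50 changed 3-fold and 84% of 50 changed 4-fold. It called 9 unchanged genes. All these changes were made in the same simulation, and genes were drawn independently, without variation that libraries share across genes. The rates may therefore overstate what the real comparison could recover. In 20 simulations without any change camera called 0 of 31 lists, and in 20 of 20 it called a list lowered by 0.4 log2; those simulations drew genes independently of each other. The alternatives were DESeq2 size factors in place of TMM, no filter on low counts, a filter at 1 CPM in 3 libraries, robust dispersion, DESeq2, limma-voom and a log2 fold minimum of 1. Others were the replicate number as a block, each library left out in turn, camera with an estimated correlation, and fry, a test of whether a list's genes move on balance in 1 direction. The fit with 1 surrogate variable was added after the data were seen. Changing TMM to size factors moved the median log2 fold change of all genes by -0.0025.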

Results

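Naive CD4+ T cells were isolated from mouse spleen and lymph nodes and cultured for 2 days under pTh17 conditions. These drive differentiation into pathogenic Th17 cells, the IL-17-producing helper T cells that the series title links to autoimmune disease. The series describes 16 libraries: 5 from wild-type mice, 5 from mice with a conditional knockout of HMGCS1, 3 Mock cultures and 3 cultures given hymeglusin. Hymeglusin is a compound that inhibits the HMGCS1 enzyme. Gene counts of the 3 Mock and the 3 hymeglusin libraries were analysed, and the 5 wild-type and 5 knockout libraries were not analysed here. The sample labels give the hymeglusin concentration as 1 mM and the series text gives it as 1 uM, so the concentration behind the hymeglusin values below is uncertain. Poly-A RNA was sequenced, and the 6 libraries held between 13750407 counts (hymeglusin replicate 3) and 16858779 counts (Mock replicate 2). Mitochondrial genes took 2.26% to 3.36% of the counts. Nothing in the labels says that the replicates came from separate mice or cultures, so the p-values below measure the spread between these libraries, which may be technical.

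The comparison of hymeglusin with Mock asks which transcripts differ when this inhibitor of the HMGCS1 enzyme is added during pTh17 culture. Whether the enzyme was inhibited in these cultures was not measured here. Hmgcs1 (ENSMUSG00000093930, GRCm38 chromosome 13, 119690379 to 119708260, plus strand) encodes the cytosolic synthase that makes HMG-CoA, a step of cholesterol synthesis. Its transcript level was 417 ± 37.4 CPM in Mock and 424 ± 29.3 CPM with hymeglusin (SD, n = 3 each). The log2 fold change was 0.02 ± 0.10 (SE), and its sign turned without Mock replicate 1 (-0.04) and without hymeglusin replicate 3 (-0.03). All 19 genes of the cholesterol synthesis list were measured. Of these, 16 had negative and 3 positive log2 fold changes, with a median of -0.08. The largest negative value was that of Ebp, a sterol isomerase (-0.27 ± 0.11 SE), and the largest positive one that of Mvk, mevalonate kinase (0.16 ± 0.12 SE). The list fell as a group in the camera test (adjusted p = 0.0446; adjusted p = 0.697 with an estimated correlation). Over all genes 0 members were called, and 0 adjusted over the list alone. The list call was made without hymeglusin replicate 3 and ended without each of the others. Its adjusted p was 0.0925 without Mock replicate 1, 0.0681 without Mock replicate 2 and 0.25 without Mock replicate 3. It was 0.0796 without hymeglusin replicate 1 and 0.691 without hymeglusin replicate 2. The call also ended without a filter on low counts (0.19) and with 1 surrogate variable (0.101). The 11 sterol uptake and SREBP2 regulation genes had a median log2 fold change of -0.04 with a mean of 0.0001 (camera adjusted p = 0.563, direction lower). Tmem97, a sterol-regulated membrane protein, had the smallest p among them (-0.15 ± 0.12 SE).

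**Figure D1:**
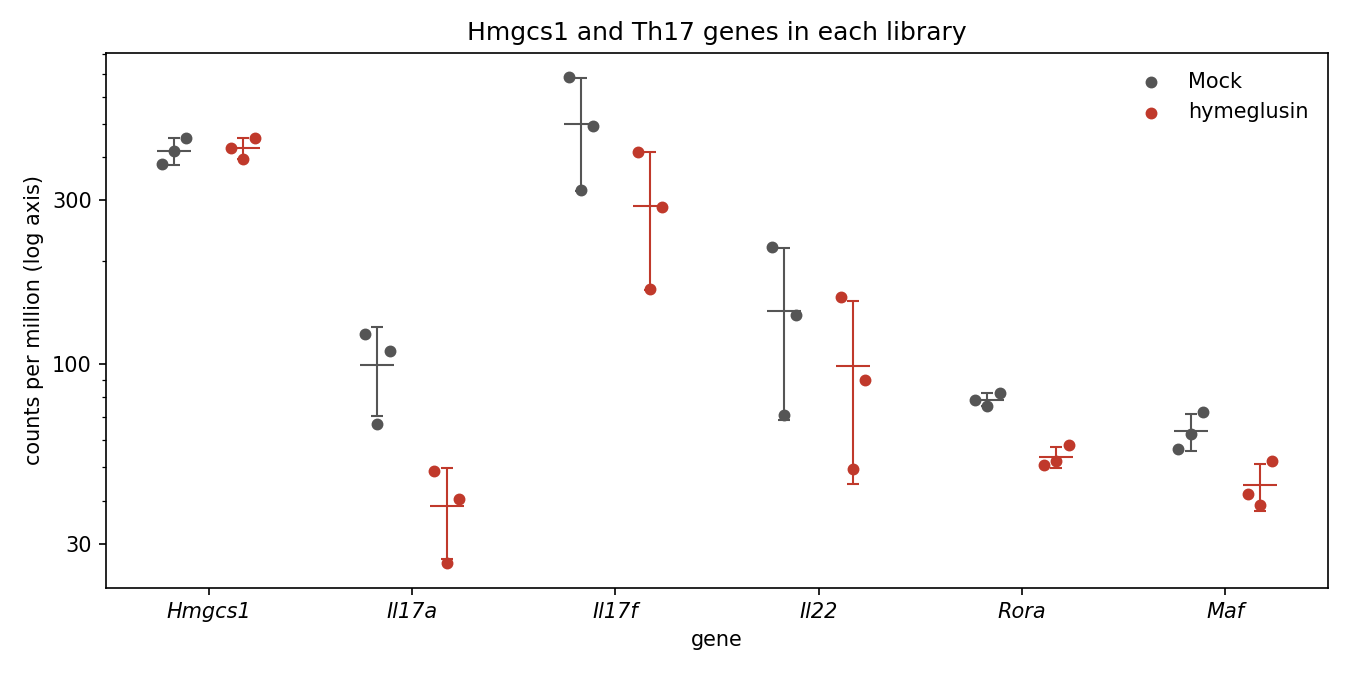
CPM (log axis) of 6 genes in the 3 Mock and 3 hymeglusin libraries; each point is a library, and the horizontal and vertical lines give the group mean and SD. Il17a lay between 67.1 and 122 CPM in Mock and between 26.3 and 48.8 CPM with hymeglusin, while the Hmgcs1 points of the groups overlapped.

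No gene passed an adjusted p under 0.05 in edgeR's quasi-likelihood test of 13264 genes (0 called; smallest adjusted p 0.834, for Ifitm3). At an unadjusted p under 0.05 there were 297 genes, 125 of them higher and 172 lower with hymeglusin. This is fewer than chance alone would give at that threshold among 13264 genes, as are the limma-voom and DESeq2 counts below. Such a shortfall does not show that nothing changed. The fit counts any shift that same-numbered libraries share as noise. Its common coefficient of variation between libraries was 0.145, against 0.0741 with the replicate number as a block. The cause of the shortfall was not tested. DESeq2 called 3 genes, which fell. These were Il17a, the gene of the cytokine IL-17A (adjusted p = 0.000312), Ifitm3, an interferon-inducible membrane protein (adjusted p = 0.000312), and Rora, a nuclear receptor of the Th17 program (adjusted p = 0.0106). limma-voom called 0 genes with 281 at an unadjusted p under 0.05, and DESeq2, run without the edgeR filter and giving 25163 genes an adjusted p, had 300 such genes. Without a filter on low counts edgeR called 17 genes, 13 lower and 4 higher. With 1 surrogate variable, an alternative chosen after the data were seen, it called 19, 16 lower and 3 higher. Both of these fits called Il17a, Il17f, Rora, Ifitm3, Timp1 and Itga3 lower and Ccl22 higher. With the replicate number as a block, a pairing that the labels do not state, edgeR called 126 genes. All 126 had the same direction in the fit without the block. In the block fit Il17a had an adjusted p of 2.04e-12. Ifitm3 was at 17.9 ± 1.46 CPM in Mock and 8.69 ± 1.08 CPM with hymeglusin (SD, n = 3 each). Ifitm2, of the same gene family, had a log2 fold change of -0.66 ± 0.16 (SE). Other genes near the smallest p were chosen after their values were seen. Their log2 fold changes were -0.79 ± 0.16 (SE) for Timp1, an inhibitor of metalloproteinases, and -0.56 ± 0.14 (SE) for Itga3, an integrin chain. They were -0.56 ± 0.14 (SE) for Plin2, a coat protein of lipid droplets, and 0.97 ± 0.23 (SE) for Ccl22, a chemokine. In each of these 4 genes, all 3 hymeglusin libraries lay on the same side of all 3 Mock libraries. Such a separation was seen in 901 of 13264 genes, 6.79%, where chance gives 10%. That share also takes no account of the replicate numbers.

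Of 17 measured Th17 core genes 16 had negative log2 fold changes with hymeglusin, with a median of -0.29. As a group the list fell (camera adjusted p = 2.24e-06; adjusted p = 0.697 with an estimated correlation). Il17a (ENSMUSG00000025929, chromosome 1, 20730905 to 20734496) was at 99.5 ± 28.9 CPM in Mock and 38.5 ± 11.4 CPM with hymeglusin (SD, n = 3 each), 0.387 of the Mock level (log2 fold change -1.37 ± 0.26 SE). Rora was at 78.7 ± 3.37 and 53.6 ± 3.86 CPM (-0.55 ± 0.09 SE). The transcription factor gene Maf was at 63.8 ± 7.90 and 44.3 ± 6.94 CPM (-0.53 ± 0.14 SE). In these 3 genes every hymeglusin library lay below every Mock library. Adjusted over the list alone, 4 members fell, these 3 among them, against 0 adjusted over all genes. The adjusted p was 0.00286 for Rora, 0.00457 for Il17a and 0.0219 for Maf. Il17f was at 499 ± 181 and 289 ± 124 CPM (-0.79 ± 0.34 SE). Il22, whose product acts on epithelia, had a log2 fold change of -0.53 ± 0.45 (SE), and Il23r, the receptor of the cytokine IL-23, one of -0.38 ± 0.28 (SE). None of these 3 genes passed the test of the 2 groups, though Il17f did without a filter on low counts (adjusted p = 0.000246) and with 1 surrogate variable (adjusted p = 0.000192). With the replicate number as a block, a pairing that the labels do not state, edgeR called all 3. The adjusted p was 2.5e-08 for Il17f, 4.99e-05 for Il22 and 0.0371 for Il23r. Relative to its mean over the 6 libraries, the list's mean log2 CPM was 0.32, -0.06 and 0.25 in Mock replicates 1, 2 and 3. It was 0.02, -0.37 and -0.16 in hymeglusin replicates 1, 2 and 3, so Mock replicate 2 lay below hymeglusin replicate 1. In the same order the B cell marker list was at -0.59, 0.32 and -0.21 in Mock and at -0.31, 0.64 and 0.15 with hymeglusin, highest in the library of each group where the Th17 core list was lowest. The difference of the Th17 core list means, -0.33 log2, had an exact two-sided permutation p of 0.2, where 3 against 3 allows no p below 0.1. That test takes no account of the replicate numbers. With the replicate number as a block the list had a camera adjusted p of 1.5e-08. The number of members called over the list alone was 2 without Mock replicate 3 and 2 without hymeglusin replicate 2. It was 8 without a filter on low counts and 8 with 1 surrogate variable.

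Of 15 measured genes of the pathogenic Th17 list, 12 had negative log2 fold changes (median -0.23). Lgals3, which encodes galectin-3, was at 49.1 ± 6.22 CPM in Mock and 34.1 ± 3.78 CPM with hymeglusin (-0.52 ± 0.13 SE). The chemokine gene Ccl4 was at 19.7 ± 1.00 and 13.9 ± 1.10 CPM (-0.50 ± 0.12 SE; SD, n = 3 each). Adjusted over the list alone, these 2 fell (adjusted p = 0.0211 each), against 0 adjusted over all genes. The list fell as a group (camera adjusted p = 0.00137; adjusted p = 0.254 with an estimated correlation). Csf2, the GM-CSF gene of this list, had 2 to 11 counts per library and was not tested. In the nonpathogenic Th17 list, 2 of 7 members fell adjusted over the list alone and 0 over all genes. These were Maf, which the core list also holds (adjusted p = 0.0271), and Il1rn, the IL-1 receptor antagonist (-0.81 ± 0.24 SE; adjusted p = 0.0305). That list did not pass the camera test (median -0.05, adjusted p = 0.137), though it was called lower without hymeglusin replicate 3 (adjusted p = 0.0248). For the other helper fates, the Th1 list of 12 genes had a median of -0.11 (adjusted p = 0.309). The Th2 list of 8 genes had a median of -0.001 with a mean of 0.09 and the direction higher (adjusted p = 0.771). The regulatory T cell list of 14 genes had a median of -0.16 (adjusted p = 0.0763). It was called lower without Mock replicate 2 (adjusted p = 0.00182) and without hymeglusin replicate 3 (0.0284). The follicular helper list of 9 genes had a median of 0.01 (adjusted p = 0.874). Tbx21, the Th1 regulator, had a log2 fold change of 0.23 ± 0.33 (SE). Its value turned to -0.01 without Mock replicate 1 and to -0.07 without hymeglusin replicate 2. Ifng had one of -0.23 ± 0.28 (SE) and Foxp3, the regulatory T cell factor, one of -0.17 ± 0.21 (SE), which turned to 0.15 and 0.03 without Mock replicate 3. Gata3, the Th2 regulator, had one of 0.36 ± 0.14 (SE), and Capg, of the regulatory T cell list, one of -0.24 ± 0.08 (SE). The naive and memory list rose as a group (camera adjusted p = 0.0173; adjusted p = 0.697 with an estimated correlation). Of its members 8 of 10 had positive values, with a median of 0.15. Tcf7, a transcription factor of naive and memory T cells, had a log2 fold change of 0.26 ± 0.10 (SE) and Ccr7, a lymph node homing receptor, one of 0.23 ± 0.10 (SE). Over the list alone or over all genes 0 members passed. That call ended without Mock replicate 2 (adjusted p = 0.181), Mock replicate 3 (0.143), hymeglusin replicate 1 (0.0832) and hymeglusin replicate 2 (0.0948). It also ended without a filter on low counts (0.106).

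**Figure D2:**
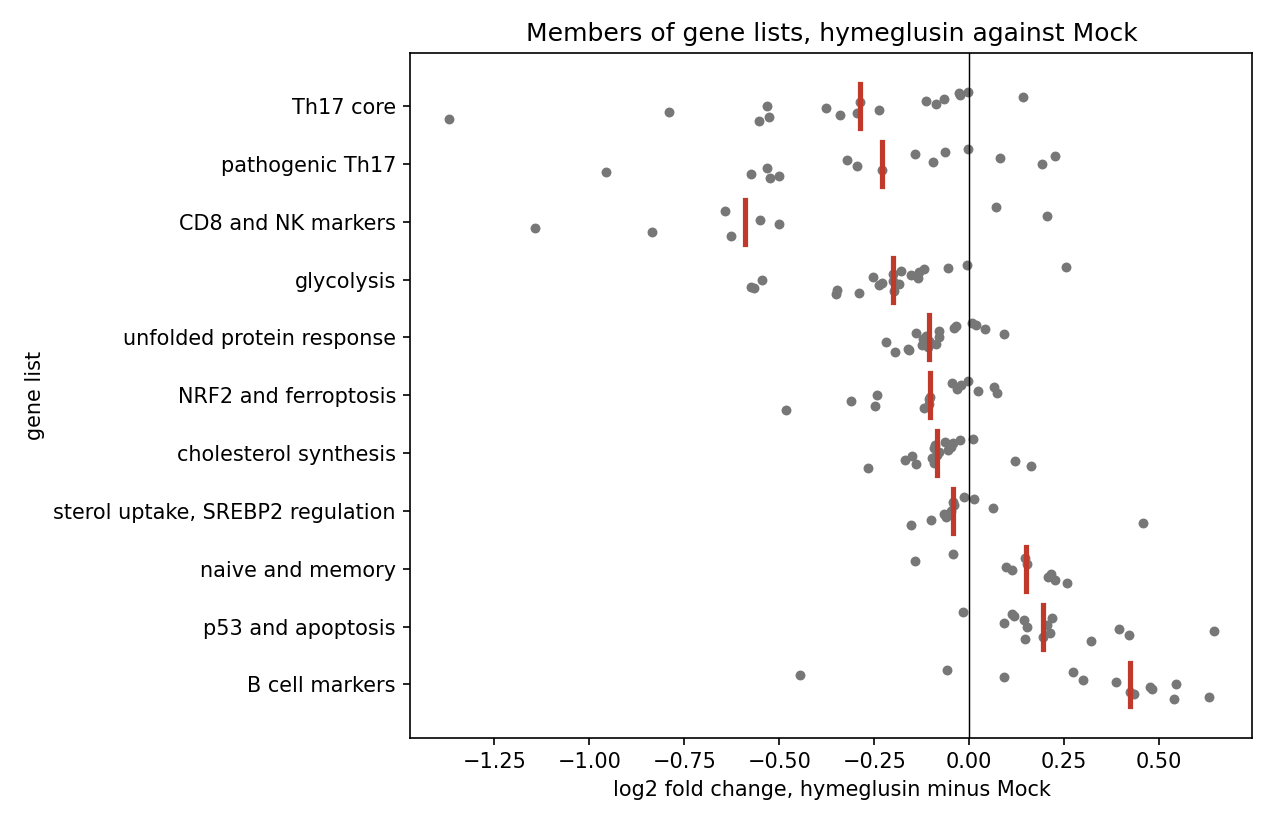
Log2 fold changes of hymeglusin against Mock (horizontal axis) for the members of 11 gene lists (vertical axis); each grey point is a gene and each red bar the median of its list. The Th17 core median lay at -0.29, that of cholesterol synthesis at -0.08 and that of the B cell markers at 0.42.

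Of 21 glycolysis genes 20 had negative log2 fold changes with hymeglusin, with a median of -0.20. The phosphofructokinase gene Pfkp was at 410 ± 77.6 CPM in Mock and 321 ± 42.6 CPM with hymeglusin (-0.35 ± 0.15 SE; SD, n = 3 each). Its muscle-type relative Pfkm had a log2 fold change of -0.29 ± 0.13 (SE), and Slc16a3, a lactate exporter, one of -0.57 ± 0.40 (SE). The exception was Gapdh (0.25 ± 0.77 SE), whose reads can be shared with its many pseudogenes. Gapdh was at 26.8, 31.3 and 120 CPM in Mock replicates 1, 2 and 3. With hymeglusin it was at 26.6, 27.2 and 159 CPM in the same order, so replicate 3 was far the highest in both groups. Its sign turned without Mock replicate 1 (-0.10), Mock replicate 2 (-0.05) and hymeglusin replicate 3 (-1.15). The list fell as a group (camera adjusted p = 0.00112; adjusted p = 0.697 with an estimated correlation), with 0 members called over all genes and 0 over the list alone. The difference of its mean log2 CPM had an exact two-sided permutation p of 0.5, a test that takes no account of the replicate numbers. With the replicate number as a block, a pairing that the labels do not state, its camera adjusted p was 5.47e-09. In that fit edgeR called Slc16a3 (adjusted p = 1.76e-05) and Pfkp (0.0103) but not Pfkm. The list call of the fit without the block ended without Mock replicate 1 (adjusted p = 0.236), Mock replicate 3 (0.0663) and hymeglusin replicate 2 (0.474). The p53 and apoptosis list rose as a group (camera adjusted p = 0.0144; adjusted p = 0.697 with an estimated correlation). Of its members 14 of 15 had positive values, with a median of 0.19. The death receptor gene Fas had a log2 fold change of 0.32 ± 0.14 (SE) and Sesn1, a p53 target, one of 0.15 ± 0.11 (SE). Its call ended without Mock replicate 1 (adjusted p = 0.381), Mock replicate 3 (0.159) and hymeglusin replicate 2 (0.691), and without a filter on low counts (0.0562). Of its members 0 passed over the list alone or over all genes. The exact two-sided permutation p of the p53 list mean was also 0.5. With the replicate number as a block the p53 list had a camera adjusted p of 5.96e-06.

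The unfolded protein response list fell as a group, with negative values in 15 of 19 members and a median of -0.11 (camera adjusted p = 0.0271; adjusted p = 0.697 with an estimated correlation). Its members Pdia6, a disulfide isomerase, and Hyou1, a chaperone, had log2 fold changes of -0.20 ± 0.11 and -0.16 ± 0.09 (SE). The call ended without Mock replicate 1 (adjusted p = 0.456), Mock replicate 3 (0.0663), hymeglusin replicate 1 (0.0636) and hymeglusin replicate 2 (0.403). It also ended without a filter on low counts (0.119). The NRF2 and ferroptosis list also fell as a group, with negative values in 12 of 15 members and a median of -0.10 (camera adjusted p = 0.0493; adjusted p = 0.697 with an estimated correlation). Srxn1, a sulfiredoxin, had a log2 fold change of -0.48 ± 0.22 (SE) and Acsl4, which activates polyunsaturated fatty acids, one of -0.12 ± 0.09 (SE). That call ended without Mock replicate 1 (adjusted p = 0.0925), Mock replicate 3 (0.48) and hymeglusin replicate 2 (0.403). It also ended without a filter on low counts (0.0899) and with 1 surrogate variable (0.311). Neither list had a member called over all genes or over the list alone (0 in each). Relative to its mean, the unfolded protein response list was at 0.13, -0.02 and 0.02 log2 in Mock replicates 1, 2 and 3. It was at 0.004, -0.13 and -0.003 in hymeglusin replicates 1, 2 and 3. The NRF2 list was at 0.05, -0.07 and 0.17 and at 0.05, -0.17 and -0.03 in the same order. Both were lowest in replicate 2 of each group, where the B cell marker list was highest (0.32 and 0.64).

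Markers of other cell types moved in both directions. B cell markers rose as a group, with positive values in 11 of 13 members and a median of 0.42 (camera adjusted p = 0.00468; adjusted p = 0.697 with an estimated correlation). Cd79a, a chain of the B cell receptor, was at 6.55 ± 1.67 CPM in Mock and 9.54 ± 3.82 CPM with hymeglusin (0.54 ± 0.30 SE; SD, n = 3 each). Fcer2a, a B cell IgE receptor, had a log2 fold change of 0.63 ± 0.37 (SE). The call ended without Mock replicate 1 (adjusted p = 0.456) and hymeglusin replicate 2 (0.474). Of the members 0 passed over the list alone or over all genes. The exact two-sided permutation p of the list mean was 0.5. The B cell, glycolysis, p53 and Th17 core lists all varied between libraries within both groups. Relative to its mean, the B cell list was at -0.59, 0.32 and -0.21 log2 in Mock replicates 1, 2 and 3. It was at -0.31, 0.64 and 0.15 in hymeglusin replicates 1, 2 and 3. The glycolysis list was at 0.36, -0.30 and 0.27 and at 0.11, -0.50 and 0.05 in the same order. The p53 list was at -0.38, 0.29 and -0.26 and at -0.11, 0.52 and -0.05. Each of these lists differed in the same direction between same-numbered libraries of the groups, which the permutation test does not use. With the replicate number as a block, a pairing that the labels do not state, camera called all of them. The adjusted p was 2.75e-06 for the B cell, 5.47e-09 for the glycolysis, 5.96e-06 for the p53 and 1.5e-08 for the Th17 core list. The CD8 and NK marker list fell as a group, with negative values in 6 of 8 members and a median of -0.59 (camera adjusted p = 0.00124; adjusted p = 0.254 with an estimated correlation). The genes behind it were those of the cytotoxic granule and NK receptors, some of which activated CD4+ T cells also express. Prf1, perforin, was at 6.36 ± 1.43 CPM in Mock and 4.12 ± 0.417 CPM with hymeglusin (-0.63 ± 0.22 SE). Klrk1, the receptor NKG2D, was at 1.80 ± 0.169 and 1.01 ± 0.326 CPM (-0.83 ± 0.35 SE). The CD8 chains Cd8a and Cd8b1, named after their values were seen, had log2 fold changes of 0.07 ± 0.46 and 0.21 ± 0.19 (SE). The sign of Cd8a turned without Mock replicate 1 (-0.04), Mock replicate 3 (-0.15) and hymeglusin replicate 2 (-0.56), in limma-voom (-0.06) and with 1 surrogate variable (-0.20). Of the list 0 members passed over the list alone or over all genes. The CD8 and NK, Th17 core and pathogenic Th17 lists were called lower in each of the 6 fits that left out a library. With an estimated correlation these calls ended (adjusted p = 0.254, 0.697 and 0.254). Of these lists fry called that of the CD8 and NK markers and neither of the Th17 lists. Markers of dendritic cells and MHC class II (8 measured, median 0.03, direction lower, adjusted p = 0.877) did not pass. Of macrophage and monocyte markers 2 genes were measured (Cd68 -0.14 ± 0.25 and Mpeg1 -0.30 ± 0.60 SE). Without Mock replicate 2 they were at 0.06 and 0.30, and Mpeg1 was at 0.11 without hymeglusin replicate 1. Of gamma delta T cell markers 1 was measured (Trdc, 0.16 ± 0.33 SE), of erythroid markers 1 (Hbb-bs, -0.15 ± 0.47 SE, turning to 0.17 without hymeglusin replicate 2), and of neutrophil and mast cell markers 0. These 4 sets were too few for the list test, as were the 4 measured sex-linked genes (median 0.08).

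**Figure D3:**
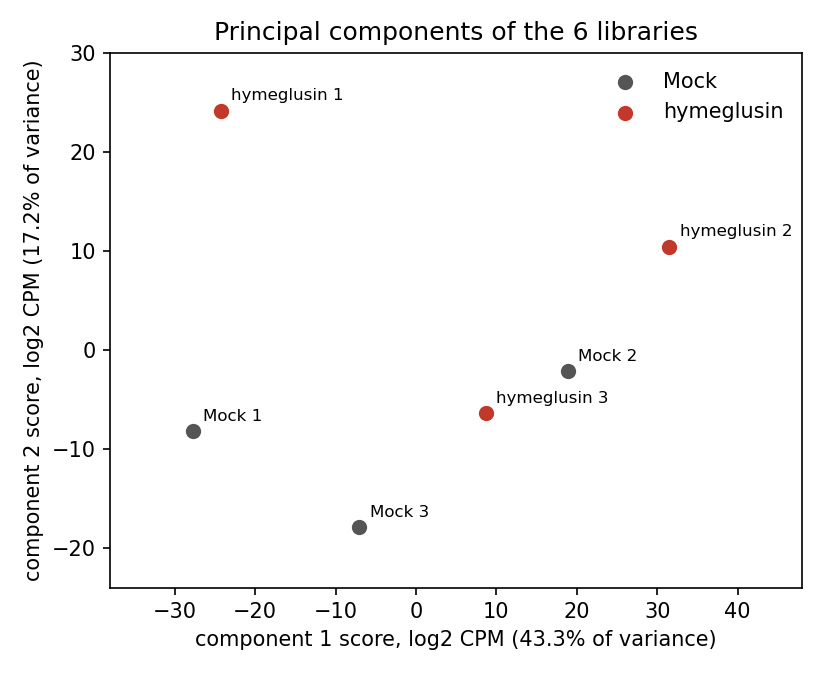
Scores of the 6 libraries on the first and second principal components of log2 CPM over 13264 genes, which hold 43.3% and 17.2% of the variance. The first component places Mock replicate 1, Mock replicate 3 and hymeglusin replicate 1 below 0 and Mock replicate 2, hymeglusin replicate 2 and hymeglusin replicate 3 above 0, so it does not separate the groups.

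In all, 10 of 31 tested lists were called by camera, 7 lower and 3 higher, and 0 with an estimated correlation. With the replicate number as a block camera called 14 lists, these 10 among them. The exact two-sided permutation p of the list means lay between 0.1 and 0.5 for these 10, where 0.1 is the smallest possible. The other 21 lists had adjusted p between 0.0763 and 0.932. Among the metabolic lists, fatty acid synthesis had negative values in 12 of 15 members (median -0.05, adjusted p = 0.0763), with the desaturase gene Scd1 at -0.30 ± 0.14 (SE). It was called lower without hymeglusin replicate 3 (adjusted p = 0.0234). Negative values were seen for LXR targets in 5 of 8 members (median -0.10, adjusted p = 0.372), for ketone bodies in 4 of 5 (median -0.07, adjusted p = 0.372) and for oxidative phosphorylation in 51 of 68 (median -0.03, adjusted p = 0.0763). The oxidative phosphorylation list was called lower without Mock replicate 2 (adjusted p = 0.0025) and without hymeglusin replicate 1 (3.35e-10). Its direction turned to higher without Mock replicate 1 (0.906), without hymeglusin replicate 2 (0.24) and with 1 surrogate variable (0.935). Prenylation and isoprenoid genes had positive values in 10 of 15 members (median 0.02, adjusted p = 0.772). Mitochondrially encoded genes had negative values in 13 of 13 members (median -0.11, adjusted p = 0.164). They were called lower without Mock replicate 2 (adjusted p = 0.00351) and without hymeglusin replicate 1 (0.00345), and turned to higher without Mock replicate 1 (0.506). The integrated stress response list had negative values in 15 of 19 members (median -0.08, adjusted p = 0.0763). It was called lower without Mock replicate 2 (adjusted p = 0.00389) and without hymeglusin replicate 3 (0.0232). Asns, asparagine synthetase, was at -0.45 ± 0.18 (SE) and Trib3, a target of that response, at -0.96 ± 0.50 (SE). The TGF-beta and SMAD list of 11 genes had a median of -0.001 and a mean of -0.08 (adjusted p = 0.877). Adjusted over the list alone 1 member of it fell, against 0 adjusted over all genes. T cell receptor activation genes had a median of 0.04 (15 genes, adjusted p = 0.483). Cd69, an early activation marker, was at 0.39 ± 0.14 (SE) and Tnfrsf9, a costimulatory receptor, at -0.28 ± 0.12 (SE). Medians were 0.02 for heat shock (11 genes, adjusted p = 0.563) and -0.01 for the cell cycle (28 genes, adjusted p = 0.856). They were 0.02 for Myc and ribosome biogenesis (20 genes, adjusted p = 0.372) and 0.03 for the interferon response (15 genes, adjusted p = 0.492). JAK, STAT3 and SOCS genes had a median of 0.02 with a mean of -0.01 (12 genes, direction higher, adjusted p = 0.932). Zbp1 of the interferon list had a log2 fold change of 0.26 ± 0.10 (SE). With a library left out, the direction of 10 lists that were called in none of those 6 fits also turned: Th2, follicular helper, prenylation, heat shock, cell cycle, Myc and ribosome biogenesis, interferon response, TGF-beta, JAK and dendritic cell. Over the 466 genes of all lists together, adjusting over those genes alone called 0 (smallest adjusted p 0.0783).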

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

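The fit with 1 surrogate variable and the counts of Th17 core members under alternatives were chosen after the data were seen. The 4-group fit of all 16 libraries was not run, since the wild-type and knockout libraries were not analysed here. The count of genes changed, 0, remained 0 with size factors, the stricter filter, robust dispersion, limma-voom, the fold minimum of 1 and in each of the 6 fits without a library (0 to 0). It was 17 without a filter, 3 with DESeq2 and 19 with 1 surrogate variable. The labels do not say that the replicate numbers pair the libraries. The deviations of same-numbered libraries correlated at r = 0.447, 0.449 and 0.0886 across genes, although all 6 libraries correlated best with their own number, a hint from the data and not the design. The common coefficient of variation between libraries that edgeR estimated was 0.145 without the replicate number as a block and 0.0741 with it. Fits without the block count any shift that same-numbered libraries share as noise. With the replicate number as a block, 126 genes (87 lower, 39 higher), 14 lists (the 10 of the fit without it and the regulatory T cell, oxidative phosphorylation, integrated stress response and mitochondrially encoded lists) and 9 Th17 core members were called. The block called 22 named genes, Il17f, Il22, Il23r, Il2 and Egln3 among them. The count of lists, 10, was 5 without a filter, 0 with an estimated correlation, 1 with fry (the CD8 and NK markers), and 3 to 14 with a library left out. It was 4 without Mock replicate 1, 4 without Mock replicate 3 and 3 without hymeglusin replicate 2. The count of Th17 core members called over the list alone, 4, was 8 without a filter, 8 with 1 surrogate variable and 2 to 5 with a library left out. For all of these the cause was not tested. Of 755 log2 fold changes of 54 named genes under the alternatives, 695 kept direction and side of the threshold, 42 passed it (22 of them with the block) and 18, of 9 genes, turned sign. Cd8a was at -0.0558 with limma-voom and -0.200 with 1 surrogate variable. With a library left out, Hmgcs1 ranged from -0.038 to 0.0918, Tbx21 from -0.0674 to 0.58, Ifng from -0.439 to 0.153, Foxp3 from -0.4004 to 0.0312, Gapdh from -1.15 to 1.28, Cd8a from -0.56 to 0.484, Cd68 from -0.319 to 0.0634, Mpeg1 from -0.689 to 0.300 and Hbb-bs from -0.568 to 0.172; the cause was not tested. Depth limits genes near the floor of 0.178 to 0.218 CPM, such as Csf2.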

Other observations

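The tests of other groupings and of a sterol depletion response were chosen after the result was seen; the tests of the library axis, of dilution, of transcript length and of depth were set out before their results. Some genes varied between libraries within both groups. Il2, the growth factor of activated T cells, was at 30.4, 73.0 and 33.8 CPM in Mock replicates 1, 2 and 3. It was at 47.3, 128 and 49.7 CPM in hymeglusin replicates 1, 2 and 3. Egln3, an oxygen-sensing hydroxylase, was at 335, 95.6 and 229 CPM and at 240, 61.7 and 152 CPM in the same order. Neither was called between hymeglusin and Mock in the fit of the 2 groups, though Il2 was without a filter on low counts (adjusted p = 0.0492). With the replicate number as a block, edgeR's quasi-likelihood test called both (adjusted p = 1.83e-05 for Il2 and 2.24e-05 for Egln3). Both genes were chosen after their values were seen.

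The Th17 core list fell with hymeglusin in camera (adjusted p = 0.697 with an estimated correlation), and the first principal component of the genes outside every list, which varies within both groups, was tested as the cause. With it as a covariate the difference of the list mean was -0.256 ± 0.047 log2 (SE), against -0.33 ± 0.16 without it, which argues against this axis as the whole cause. Dilution of the T cells by other cells is argued against by 17 T cell identity genes (Cd3e, Cd4, Lck and others), whose median log2 fold change was -0.0261 (95% bootstrap interval over genes -0.05 to 0.04) against -0.29 for the Th17 core list, although the B cell markers had a median of 0.42. That interval resamples genes of the same 6 libraries and does not measure the spread between libraries. The 10 splits of the 6 libraries are too few for a share under 0.05: 1 split, the real one, gave a camera p as small as 7.21e-08 (smallest of the others 3.08e-05), 2 of 10 called as many lists as the 10 of the real one (highest other 13), and all 10 necessarily called as many genes as the 0 of the real one (highest other 1399), a comparison that decides nothing. An effect of hymeglusin stays open, and no test here decides it.

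Among the 10 splits, that of Mock replicates 1 and 3 and hymeglusin replicate 1 from the other libraries called most genes, 1399, which points to a structure of the libraries that the groups do not hold. It was picked for that count and follows the sign of the first principal component, so the count restates the variance of that component. Gene length may contribute, since the fold changes of that split correlated with it across genes (Spearman 0.273, genes not being independent), but after removal of each library's trend on length 1134 genes were called, 981 of them among the 1399. A difference in depth is argued against by thinning every library to 13750407 counts, after which 1420 genes were called, 1323 of them among the 1399. The labels name no batch or culture day for these libraries, and no biological explanation was tested.

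Inhibition of HMGCS1 could be expected to deplete sterols and raise the genes of sterol synthesis and uptake. The median log2 fold change of the 30 such genes was -0.0625 (95% bootstrap interval over genes -0.09 to -0.04). That interval resamples genes and does not measure the spread between libraries. The mean log2 CPM of the synthesis list was 6.77 ± 0.03 in Mock and 6.70 ± 0.09 with hymeglusin (SD, n = 3 each). That of the uptake and SREBP2 regulation list was 6.42 ± 0.02 and 6.42 ± 0.06. These values argue against such a response in the transcripts of these libraries after 2 days. Whether the enzyme was inhibited was not measured here, and the concentration is uncertain.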
